A study of Aplysia californica with 3 samples.

How the data were processed

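Total RNA of L7 neurons and of sensory clusters of Aplysia californica was amplified in 1 round to cRNA, labelled with Cy3 (L7) or Cy5 (sensory cluster) and hybridised in pairs to 3 arrays, per the labels' protocols. The protocols name a direct and an indirect labelling method without saying which array had which. The authors deposited the scanner output of each array, with 42034 probe spots, 1942 positive and 314 negative control spots. The spot and background brightness are intensity values on a linear scale, per the file headers. The scanner software's processed signals are intensity values after background and dye correction, per the file headers. Its log ratio is the log10 of Cy5 over Cy3, that is sensory cluster over L7, per the file headers. The deposited value table of the series holds the same log10 ratio rounded, with the same direction and no further centring, and its column medians were 0, -0.008 and 0. Flags of each spot (above background, saturated, outlier) are deposited as other values of 0 or 1.

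Mean spot intensity was background corrected with normexp (offset 50), and each array was normalised by loess with control and outlier-flagged spots at weight 0, in limma 3.58.1 under R 4.3.3. Flagged spots were left out and the spots of a probe were averaged. Of 41504 probes, 37437 were well above background in at least 1 channel on all 3 arrays and 37367 of them had a value on each. The log2 ratio of L7 over sensory cluster was tested against 0 with lmFit (intercept only) and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Because all arrays had the same dye orientation, no dye term could be fitted. Each array is 1 replicate, and neither a slide nor a scan date was used as a batch. Saturated spots were kept. All named probes were well above background in both channels on all 3 arrays and none was saturated on all 3. The probe UF_Ac_100049_f1 and FMRFamide had a saturated sensory cluster signal on 1 array, where that signal is only a minimum.

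Gene names came from the array files. Of 122 accession-like strings in those names, 0 matched the reference table of AplCal3.0, so unnamed probes stayed unnamed, and no coordinates are given. Readable names covered 43 genes with 141 probes, of which 131 were tested. A gene is represented by its brightest tested probe. Of the readable genes, 1 entered the computation and is not reported here. In 16 of the 42 others the tested probes had both signs, and these were AcCYFIP, actin, beta-tubulin, cad1, cad2, choline acetyltransferase, coproporphyrinogen oxidase, Fasciclin, FMRFamide, neurotransmitter transporter, nitric oxide synthase, Panx-2, Panx-3, Panx-4, serine dehydratase and soluble guanylate cyclase. Gene lists fixed before the data were examined numbered 21 and were matched to names after the joining characters in names were read as spaces. Of these, 10 had a measured member and 2 had at least 5, which were tested with camera (preset correlation 0.01) among the readable genes. The 11 lists with no member were synaptic vesicle and exocytosis, cytosolic ribosomal proteins, translation factors, mitochondrial respiration, glycolysis, ubiquitin and proteasome, chaperones, transcription factors and chromatin, lysosome and proteolysis, antioxidant and iron handling, and ciliated cell markers. Display names and the grouping in the plot of readable genes were set after the names were seen and before any ratio was computed.

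Genes to name were fixed in advance: readable genes past the threshold with the same sign on all arrays, up to 12 per direction, the 3 members of each list with the smallest p, sensorin, passing neuropeptide precursors, choline acetyltransferase and vesicular transporters where measured, and the 2 largest unnamed probes per direction. The procedure was tested on simulated data of 37367 probes for this comparison with 200 changed probes. It recovered 5 of 71 probes changed 2-fold (7.04%), 63 of 71 changed 4-fold (88.7%) and 57 of 58 changed 8-fold (98.3%). Beside these true calls there were 12 false calls. The real comparison called 799 probes, more than the 200 changed in the simulation. Recovery under the Benjamini-Hochberg adjustment depends on how many probes change, so these rates may not hold for the real data. Alternatives covered background correction, dye normalisation, filters, flags, the variance model, a size threshold, the deposited value table and leaving out each array. Regression on base composition, all probes of a gene averaged, probes saturated on any array left out, all gene names as the set background and the alternatives of the array correlations were added after the data were seen.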

Results

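RNA of L7, an identified motor neuron of the abdominal ganglion of the sea slug Aplysia californica, was set directly against RNA of a sensory cluster, a group of sensory neurons, on two-colour 60-base oligonucleotide arrays. There were 3 arrays, named here replicates 1 to 3, each holding 1 L7 sample in Cy3 and 1 sensory cluster sample in Cy5, and the series describes them as biological replicates. The median spot brightness was 94.9 for L7 and 139 for the sensory cluster in replicate 1, 197 and 476 in replicate 2, and 213 and 249 in replicate 3. By the scanner software's flag, L7 signal was well above background for 89.6% of the 41504 probes in replicate 1, 94.2% in replicate 2 and 94.2% in replicate 3, and sensory cluster signal for 87.4%, 97.9% and 95.2%. Of 13332 sequences with a probe for each strand, 10810 had both probes tested. The flag alone therefore does not show that a transcript was present. The number of arrays limits the precision of every ratio given here. Most probes carry only a contig number, and 43 genes with a readable name were tested.

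The comparison asked which transcripts differed in abundance between the motor neuron and the sensory cells. Among the readable genes, Tolloid and GABA-A receptor alpha were higher in the sensory cluster, and no readable gene passed the test in the L7 direction. Tolloid, a secreted metalloprotease of the extracellular matrix, was 6.48-fold higher in the sensory cluster, with a log2 ratio of L7 over sensory cluster of -2.70 ± 0.97 (SD, n = 3 arrays; limma adjusted p = 0.0463). GABA-A receptor alpha, named for a subunit of the chloride channel opened by the inhibitory transmitter GABA, was 1.96-fold higher in the sensory cluster, at -0.97 ± 0.023 (SD, n = 3; limma adjusted p = 0.0260). The SD of 0.023 overstates the precision of this ratio. The 95% interval of the limma test reached 0.27 to either side for GABA-A receptor alpha and 0.97 for Tolloid. All 3 arrays gave both genes the same direction, which a call with 3 arrays at the threshold used here requires, so it adds no support. Tolloid was read by 3 different probes at -3.04, -2.70 and -1.48, of which 2 passed the threshold, and GABA-A receptor alpha by 2 tested probes at -0.97 and -0.69, of which 1 passed. Tolloid lost its call when dim probes were also tested (adjusted p = 0.0592), with its log2 ratio unchanged at -2.70. Both lost it without replicate 2 (Tolloid adjusted p = 0.0809, GABA-A receptor alpha 0.0741) and without replicate 3 (0.178 and 0.204). The log2 ratios were then -2.25 and -2.62 for Tolloid and -0.98 and -0.96 for GABA-A receptor alpha. With the scanner software's processed signals the log2 ratios were larger, at -3.87 for Tolloid and -1.94 for GABA-A receptor alpha.

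Over all tested probes, 358 were higher in L7 and 441 were higher in the sensory cluster, of 37367 tested, by limma at an adjusted p under 0.05. All 799 called probes had the same sign on all 3 arrays, but a call at this threshold with 3 arrays already requires that. The median size of the log2 ratio of the called probes was 1.47. In 309 of the L7 probes and 330 of the sensory cluster probes the difference was at least 2-fold. When each array was centred on its median in place of loess, 533 probes were higher in L7 and 3324 in the sensory cluster, so the share of called probes higher in L7 was 13.8% in place of 44.8%. With the processed signals 661 and 866 probes were called. Without replicate 3, 72 and 64 probes were called, and without replicate 2, 233 and 173. L7 carried Cy3 on every array, so no array with swapped dyes corrects for a dye effect. Sensory cluster signal was saturated on at least 1 array for 11 of the 358 probes called higher in L7, and there that signal is only a minimum. It was saturated on all 3 arrays for 8 of the 358, and the direction of these 8 is not settled.

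**Figure D1:**
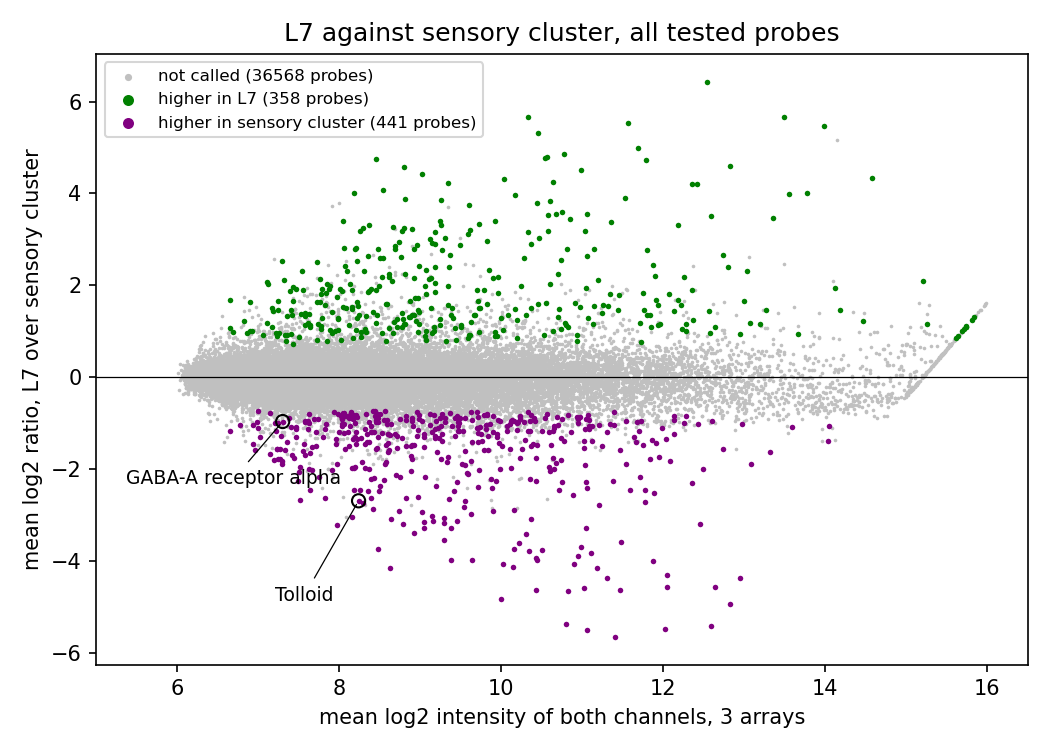
Each point is 1 of the tested probes, with the mean log2 intensity of both channels over the 3 arrays on the x axis and the mean log2 ratio of L7 over sensory cluster on the y axis. Green points are the 358 probes higher in L7, purple points the 441 higher in the sensory cluster and grey points those not called. The diagonal edge at the bright end holds probes whose sensory cluster signal was saturated, and Tolloid and GABA-A receptor alpha are circled.

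The largest ratios belonged to probes without a readable name. The probe UF_Ac_140005_c1 (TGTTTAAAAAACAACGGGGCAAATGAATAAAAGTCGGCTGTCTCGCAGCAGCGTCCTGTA) was 86.3-fold higher in L7, with a log2 ratio of 6.43 ± 0.90 (SD, n = 3; limma adjusted p = 0.00622). The probe UF_Ac_121443_c1 (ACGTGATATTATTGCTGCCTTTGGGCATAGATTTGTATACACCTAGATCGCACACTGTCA) was 50.8-fold higher in L7, at 5.67 ± 0.24 (SD, n = 3; limma adjusted p = 0.00394). In the other direction, UF_Ac_100049_f1 (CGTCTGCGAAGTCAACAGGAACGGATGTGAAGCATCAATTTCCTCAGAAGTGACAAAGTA) had a log2 ratio of -5.66 ± 1.16 (SD, n = 3; limma adjusted p = 0.0138), with a saturated sensory cluster signal on 1 of the 3 arrays, so that the size of this ratio is a lower bound and its SD and rank are inexact. UF_Ac_134610_c1 (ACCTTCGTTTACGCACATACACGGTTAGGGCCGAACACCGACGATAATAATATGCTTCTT) was 45.4-fold higher in the sensory cluster, at -5.50 ± 0.52 (SD, n = 3; limma adjusted p = 0.00448). UF_Ac_100049_f1 lost its call without replicate 3 (log2 ratio -5.54, limma adjusted p = 0.0549) and was at -6.29 without replicate 1. With median centring UF_Ac_140005_c1 was at 5.69, UF_Ac_121443_c1 at 5.16, UF_Ac_100049_f1 at -6.29 and UF_Ac_134610_c1 at -6.10. All 4 probes were well above background in both channels on every array. The array files give UF_Ac_100049_f1 a public sequence record with no gene name and the other 3 a contig number, so the genes they read are not named in the sources used here.

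Of the 5 measured transmitter receptors, 1 passed over all probes, GABA-A receptor alpha, and 4 passed when adjusted over the list alone, in both directions. AMPA receptor, a channel for the excitatory transmitter glutamate, had a log2 ratio of 0.87 ± 0.33 (SD, n = 3; limma adjusted p = 0.0782) and was above 0 in its 3 probes and on all 3 arrays. With the processed signals it was at 1.54 and passed (limma adjusted p = 0.0417). NMDAR1-1, another glutamate receptor subunit, was at 0.46 (limma adjusted p = 0.199), and at 0.18 with median centring. The non-alpha nicotinic acetylcholine receptor was at -0.44 (limma adjusted p = 0.138). P2X4-2, named for a family of ATP-gated channels, was at 0.03, and at -0.01 with median centring. The receptors as a set did not stand apart from the other readable genes (camera adjusted p = 0.525, and adjusted p = 0.581 with an estimated correlation). Their median was 0.03 and their mean -0.01, so the list had no single direction.

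Of the 6 measured genes of transmitter synthesis and transport, none passed by limma over all probes, where 7801 probes had an unadjusted p under 0.05, and 2 passed when adjusted over the list alone. Those were nitric oxide synthase 2, which makes the gaseous messenger nitric oxide, at 0.46 ± 0.11 (SD, n = 3; limma adjusted p = 0.125), and dopamine beta-hydroxylase, an enzyme of catecholamine synthesis, at 0.44 ± 0.11 (SD, n = 3; limma adjusted p = 0.134). Choline acetyltransferase, which makes acetylcholine, was at -0.0034 ± 0.12 (SD, n = 3; limma adjusted p = 0.989), with another probe at 0.07, and at -0.38 with median centring. The neurotransmitter transporter was at 0.12 (limma adjusted p = 0.573), with another probe at -0.07, and at -0.34 with median centring. The list median was 0.13, and -0.14 with median centring, and the set did not stand apart from the other readable genes (camera adjusted p = 0.525, and adjusted p = 0.581 with an estimated correlation).

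The other lists fixed before the data were examined had at most 2 measured members and were not tested as sets. The ion channel list held the nicotinic receptor alone, because its patterns did not match the names of other channels on the array. The plot of readable genes groups 7 ion and gap junction channels, of which 0 were called. The list of cAMP, calcium and kinase signalling held Tolloid alone. The neuropeptide list held FMRFamide, at 1.10 ± 0.95 (SD, n = 3; limma adjusted p = 0.199) with probes that ran from -0.14 to 1.10, and a neuropeptide precursor at -0.04 (limma adjusted p = 0.902). FMRFamide was at 0.18 with median centring and at 0.55 without replicate 1, and its sensory cluster signal was saturated on 1 array, where the ratio is an upper bound. The array file gives the entry named FMRFamide the same sequence record as the entry named Vanilloid, so its identity is unsure. Sensorin, the peptide of the mechanosensory neurons, is not named on the array. PC2, a protease that cuts peptide precursors, was at 0.55 ± 0.78 (SD, n = 3; limma adjusted p = 0.357), and its 6 probes all lay above 0, from 0.52 to 1.50. With median centring the brightest PC2 probe was at 0.11, and without replicate 1 at 0.19. That probe was at -0.28 in replicate 2, while the other PC2 probes were above 0 on every array. None of them passed, the nearest being at 0.79 (limma adjusted p = 0.0527) and 1.50 (limma adjusted p = 0.0618). Staufen, an RNA-binding protein, was at 0.18 (limma adjusted p = 0.511), and at -0.38 with median centring. Of the cytoskeletal genes, actin was at 0.29 ± 1.26 (SD, n = 3; limma adjusted p = 0.739) and beta-tubulin at -0.07 ± 0.43 (SD, n = 3; limma adjusted p = 0.852). With median centring they were at -0.38 and -0.72. The probes of each had both signs, down to -0.04 for actin and up to 0.05 for beta-tubulin. Actin was at -0.23 without replicate 1 and at 0.99 without replicate 2, and beta-tubulin was at 0.18 without replicate 2.

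Markers of other cell types were few. Twitchin-like, named for a giant muscle protein, was at 0.41 ± 0.46 (SD, n = 3; limma adjusted p = 0.310) and at 0.13 with median centring, and hemocyanin, the oxygen carrier of the blood, was at 0.19 ± 0.16 (SD, n = 3; limma adjusted p = 0.405). Neither passed the test.

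**Figure D2:**
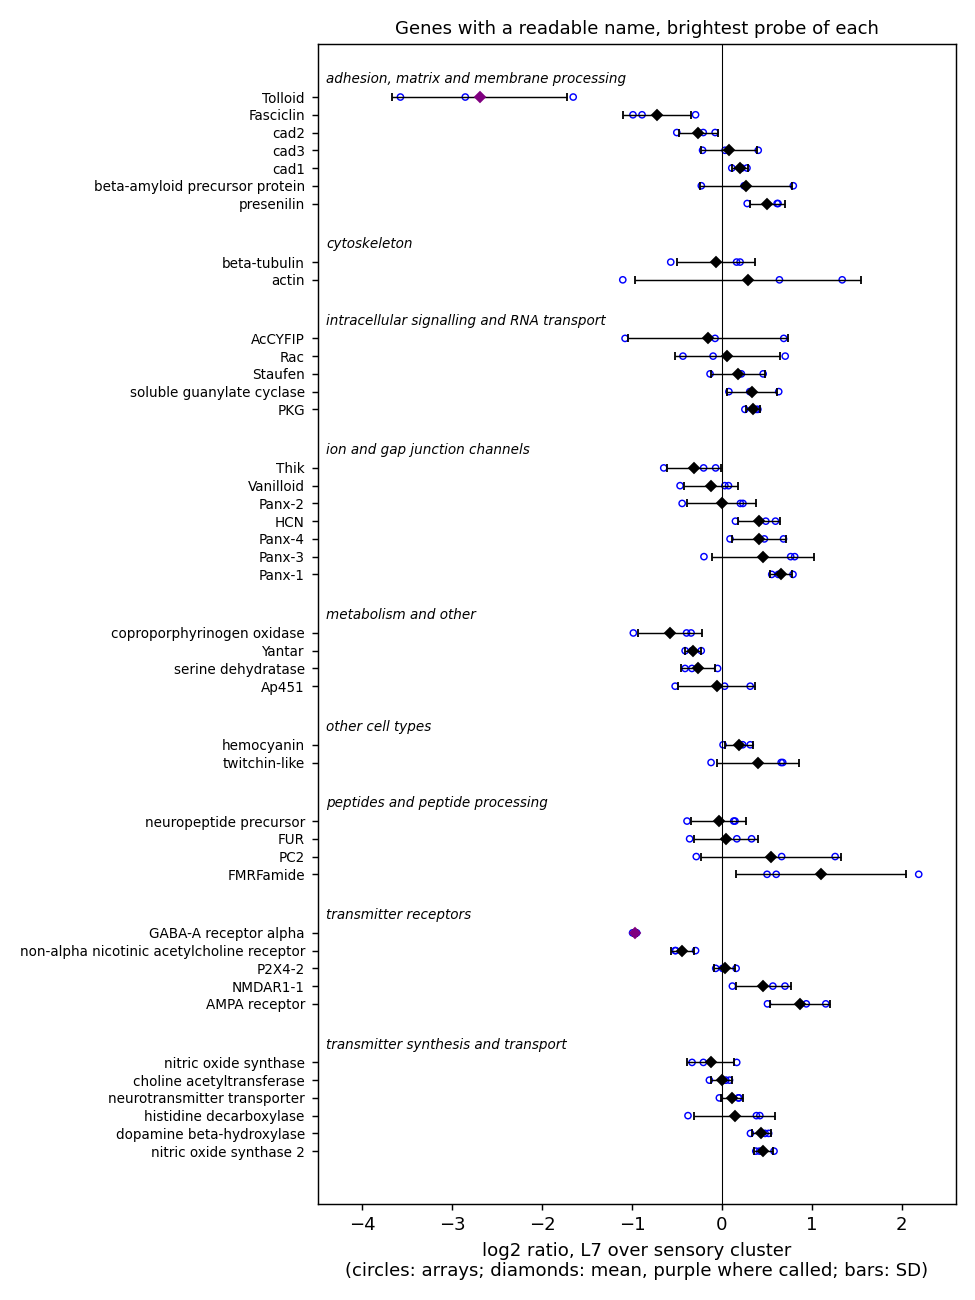
The log2 ratio of L7 over sensory cluster of 42 readable genes is on the x axis, with the genes grouped by kind. Circles are the 3 arrays, diamonds their mean and bars the SD, and Tolloid at -2.70 and GABA-A receptor alpha at -0.97 are the called genes.

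The log2 ratios of the arrays correlated across the 37367 probes with a Pearson r of 0.44 between replicates 1 and 2, 0.58 between replicates 1 and 3, and 0.70 between replicates 2 and 3. Probes are not independent replicates, so no p is given. All 3 correlations were above 0, which a dye effect would also give, since L7 carried Cy3 on every array.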

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

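The base composition, saturation, probe-averaging and set-background alternatives and those of the array correlations were chosen after the data were seen. No probe called in the reported analysis was called in the opposite direction under any alternative. The number of probes higher in L7 was 589 with normexp offset 10, 661 with the scanner software's processed signals and 663 with the value table, and the number higher in the sensory cluster was 762, 866 and 870. Median centring gave 3324 higher in the sensory cluster. It leaves in place the trend of the ratio with brightness that loess removes. The bright Ap451 went from -0.06 to -0.82 and beta-tubulin from -0.07 to -0.72. The dimmer GABA-A receptor alpha went from -0.97 to -0.95 and AMPA receptor from 0.87 to 0.93. Whether that trend came from the dyes or from the cells was not tested. Leaving out 1 array gave 72 (without replicate 3) to 462 (without replicate 1) probes higher in L7 and 64 to 568 higher in the sensory cluster. The counts stayed within 1.5 times under the other alternatives, with 345 and 438 once probes saturated on any array were left out. Aquantile moves no log ratio, so its equal counts say nothing about stability. Tolloid kept its direction under every alternative, from -3.87 to -2.25, and lost its call without the filter on dim probes and without replicate 2 or 3. GABA-A receptor alpha ran from -1.94 to -0.83 and lost its call without replicate 2 or 3. AMPA receptor passed in the L7 direction with normexp offset 10 (adjusted p = 0.0471), the processed signals (0.0417), median centring (0.0215), the value table (0.0415) and a robust intensity trend (0.0451), over a range of 0.0215 to 0.338. With median centring coproporphyrinogen oxidase (-1.35), Fasciclin (-1.41) and Yantar (-0.79) passed in the sensory cluster direction. The other probes of the first 2 lay on the L7 side in the reported analysis (0.45 and 0.33 for coproporphyrinogen oxidase, 0.19 and 0.07 for Fasciclin), and the mean over all probes of coproporphyrinogen oxidase was 0.07. Neither gene list passed under any set test, and fry gave an adjusted p of 0.0515 for both. The correlation of replicates 1 and 2 was 0.58 with median centring, against 0.44. Signal over background limits dim probes most, where the offset pulls ratios toward 0.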

Other observations

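The tests of opposite strands, of turned array signs and of cell-type markers were chosen after their results were seen, and the base composition tests after base content had been seen to correlate with the log ratios but before the regressions were run. The 5 readable genes that follow had the same sign on all 3 arrays and were chosen after their values were seen, so they stand for no group. Panx-1, named for the pannexin family of membrane channels, was at 0.66 ± 0.12 (SD, n = 3; limma adjusted p = 0.0695), with its 3 probes from 0.05 to 0.66. HCN, named for a family of cation channels opened by hyperpolarization, was at 0.41 ± 0.23 (SD, n = 3; limma adjusted p = 0.195), and all 3 of its probes lay above 0. Thik was at -0.31 ± 0.30 (SD, n = 3; limma adjusted p = 0.316), with its 3 probes from -0.31 to -0.21, and at -0.07 with median centring and -1.06 with the processed signals. Fasciclin, a cell adhesion protein, was at -0.72 ± 0.38 (SD, n = 3; limma adjusted p = 0.124), but its probes ran from -0.72 to 0.19. Presenilin, part of a protease within membranes, was at 0.51 ± 0.20 (SD, n = 3; limma adjusted p = 0.130). None of these 5 passed the threshold. With median centring Panx-1 was at 0.30, HCN at 0.14 and presenilin at 0.03, and Fasciclin was at -1.41 and passed (adjusted p = 0.0219, over a range of 0.0219 to 0.467). Of the 43 readable genes, 4 passed when adjusted over the readable genes alone, which were Tolloid, GABA-A receptor alpha, Panx-1 and AMPA receptor.

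Many contigs were printed as a pair of probes, 1 for each strand, and 10810 such pairs were tested. At least 1 probe was called in 498 pairs, and in 375 of these (75.3%, exact 95% interval 71.3 to 79.0) the partner had the same sign, against 55.3% of pairs with no call. The interval treats the pairs as independent, but all pairs were read on the same 3 arrays. Both probes were called in 20 pairs, with the same direction in 20 and opposite directions in 0. A dye bias that the probes of a pair do not share would leave partners without a shared sign. Such a bias is argued against as the whole source of the called probes. The pairs cannot address a dye bias that both probes share, as through base content or brightness. Base composition explained 0.171%, 5.88% and 10.2% of the variance of the log ratios in replicates 1 to 3, and after it was regressed out 90.2% of the called probes were called in the same direction, which argues against it as the whole source too. When the sign of 1 array was turned, limma called at most 0 probes, with 975, 459 and 166 at an unadjusted p under 0.05, against 799 called in the real orientation. As many were called in 1 of the 4 orientations, and 4 are too few for a share under 0.05. A dye effect shared by a whole transcript stays open, since no array had the dyes swapped, beside a difference between the cells, which was not tested apart from it.

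For Tolloid, base composition gave at most 9.76% of the log2 ratio in any of its 3 probes, which argues against it as the source. Cells of the sheath, muscle or blood in the sensory cluster sample stay open as a possible explanation. The markers on the array were twitchin-like at 0.41 (95% interval -0.11 to 0.92) and hemocyanin at 0.19 (-0.12 to 0.49), neither lower in L7, but 2 markers do not stand for all other cell types.

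Replicate 1 correlated less with the others, at a mean r of 0.51, than replicates 2 and 3 with each other at 0.70. Over the 9342 probes brightest on replicate 1 its mean r was 0.59, from 0.52 and 0.65, against 0.70. This gap of 0.11 is over the bound of 0.05 set for the mean before the test, which argues against dim signal as the whole source. The gap over all probes was 0.19. After base composition was regressed out its mean r was 0.53, against 0.69, which argues against base composition as the whole source. The labels do not say which array had direct or indirect labelling, so the labelling method could not be tested. The correlation of replicates 1 and 2 also depended on the normalisation, as it was higher with median centring.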
